A study of Mus musculus with 2 samples.

How the data were processed

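The measurements were gene counts of single cells from the epithelium of the proximal small intestine of C57BL/6 mice. There were 2 libraries, both in the control group. The series concerns mice with less of the M1 or the M3 muscarinic acetylcholine receptor, and per its design text control animals supplied the single cell suspensions; the libraries are named here control 1 (titled as an M1 control) and control 2 (titled as an M3 control). Per the labels' protocols, opened tissue was held in ice-cold 20 mM EDTA for 60 min to release a villus fraction and then in TrypLE, a trypsin-like enzyme, for 10 min to release a crypt fraction. Both fractions passed a 30 µm strainer and were pooled, and suspensions of at least 80% viability went into 10x Genomics Chromium 3' libraries, which read polyadenylated RNA near its 3' end with a unique molecular identifier (UMI) per molecule. Per the file headers, the deposited values are whole-number UMI counts per gene and cell barcode, written by Cell Ranger 7.1.0. Per the submitters' processing notes, Cell Ranger 6.1 and 7.1.0 and the builds GRCm38 and mm10 were used, and which version made which step was not given in the sources used here. The rule by which the authors kept barcodes, the annotation release and whether reads in introns were counted were not given in the sources used here either. Both files hold 32285 genes, and the lowest barcode total is 500 UMIs in each.

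Control 1 held 9342 barcodes with 54451793 UMIs and control 2 held 7109 barcodes with 36139325 UMIs. Barcodes with under 500 genes (1719 in control 1, 2094 in control 2) or with 25% or more mitochondrial UMIs (828 and 685) were left out; hemoglobin made up over 50% of the UMIs in 488 and 661 of the former. Scrublet in scanpy 1.11.5 was run per library with an expected doublet rate of 0.06. It marked 5 of 7120 barcodes (0.0702%) in control 1, so the doublet caller did not work there, and 28 of 4742 (0.590%) in control 2. Kept were 7115 cells with 44907552 UMIs and 4714 cells with 27149001 UMIs, of which 100 and 41 held over 50000 UMIs. Multiplets were therefore mostly not removed, and an alternative without the 6% of cells with the highest Scrublet scores was added after the data were seen.

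Cells were clustered jointly (Leiden, resolution 1.0, 40 principal components, 2000 most variable genes ranked across libraries, 15 neighbours, counts scaled to 10000 UMIs per cell and log-transformed). Mitochondrial genes, ribosomal protein genes and the 322 measured genes of 19 fixed lists were kept out of the clustering. The 25 clusters were named from 136 marker genes fixed beforehand, and names end in "-like" because they rest on these markers alone. The markers were fixed before the data were examined, while the scoring rule that turns them into names was set afterwards: a cluster took the class with the highest mean marker score among those with at least 3 detected markers. It stayed unnamed where more of its 10 leading genes marked another class, where none marked its own class and the score was low, or where none did and its cells were shallow. A cluster of 39 cells led by Siglech, a plasmacytoid dendritic cell gene, stayed unnamed. The rule merges stem and cycling progenitor clusters as progenitor-like; at this resolution both merged clusters were named cycling progenitor and none was named stem. Genes used for clustering or naming have no test results here. Levels of some of them describe the libraries (Defa36, Mcpt1, Ido1) or serve as checks of the cells (Lgr5, Olfm4, Neat1, Muc2).

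For each epithelial class, the UMIs of its cells were summed per library and set against the summed UMIs of all other named epithelial classes of that library, which makes 2 sums against 2. The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3; TMM, filterByExpr, library as a block because the classes of a library come from the same suspension), with Benjamini-Hochberg adjustment over all tested genes that were not used to cluster or name cells, and again over each list alone; the threshold was an adjusted p of 0.05. As designed, the test covered the classes with at least 20 cells in each library (enterocyte, progenitor and goblet). The Paneth, enteroendocrine and tuft classes were tested as an addition chosen after the data were seen, with at least 5 cells in each library. Cells are not replicates. The labels do not say that the libraries came from separate animals. With library as a block, the p-values measure only how far the class-to-rest ratio differed between these 2 libraries, a spread that may be technical. The fit has 1 residual degree of freedom per gene before edgeR shares the spread across genes. That sharing was done separately for each class, so p-values cannot be ranked between classes. Whatever differs between an M1 control and an M3 control cannot be told apart from library. Tested on simulated data drawn from the real sums with trended spread between libraries and 200 changed genes, the test recovered 85 of 100 genes changed 4-fold and 34 of 100 changed 2-fold for the enterocyte class (12844 genes, 3 false calls among 122), 90 and 50 for the progenitor class (12923 genes, 4 among 144), 87 and 41 for the goblet class (12244 genes, 8 among 136), 56 and 3 for the Paneth class (11884 genes, 0 among 59), 53 and 6 for the enteroendocrine class (12798 genes, 2 among 61), and 28 and 1 for the tuft class (11952 genes, 2 among 31). The simulated changes were few and balanced in direction. In the real enterocyte class 3405 of 11727 tested genes were higher and 2977 lower. The false calls therefore do not show the error rate under such large differences between classes.

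Levels are given as CPM, UMIs of the gene scaled to the UMI total of the class, with exact 95% Poisson intervals, and shares with exact Clopper-Pearson intervals; both cover counting error only. A ± after a mean CPM is the standard deviation over the 2 libraries, and a ± after a log2 fold change is the standard error of the fit. A count of 0 allows up to 3 counts, and a fold against 0 is a lower bound against 3 counts over both libraries together. Shares of cells with a UMI were also computed for cells thinned to 2000 UMIs, from the exact probability that a UMI of the gene stays, with shallower cells left out. T or NK cell-like clusters served as a class outside the epithelium for receptor shares, a choice not among those fixed before the data were examined. Between the libraries there is 1 value on each side and hence no test and no replicate check: genes were counted where CPM differed at least 4-fold with at least 50 UMIs in the library where they were higher, and log2 ratios used a pseudocount of 1 CPM. Coordinates are from GENCODE M21 on GRCm38, a build named in the submitters' processing notes; the annotation release behind the deposited counts may differ.

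The genes named in the text follow a rule fixed before the data were examined: Chrm1 to Chrm5 in every epithelial class; from each list up to 4 genes with an adjusted p under 0.05 and the same direction in both libraries, those with the largest fold changes, at most 30 genes per class; and between libraries the 10 largest ratios in each direction plus the list genes past the size rule and the sex-linked list. Exceptions, named after their values were seen, are Mttp, Apob, Slc5a1 and Cd74 in the enterocyte class, Cftr, Notch1, Sox4 and Sox9 in the progenitor class, Gnaq, Itpr3, Ache, Gbp2, Cd74, Chrnb1, Gna11 and Plcb3 in the goblet class, Notch1 and Sox9 in the Paneth class, and Ffar1 in the enteroendocrine class. A gene that the rule picked is not reported here; it was not replaced, and the list counts keep it. The lists cover muscarinic receptors, acetylcholine handling, nicotinic receptor subunits, Gq and calcium signalling, Gi and adenylyl cyclase, ion transport and fluid secretion, gut hormones, hormone and nutrient receptors, sugar and amino acid transporters, lipid and bile acid handling, ErbB ligands and receptors, Wnt and Notch niche, secretory lineage transcription factors, class II antigen presentation, Reg and inducible defence, interferon response, xenobiotic metabolism, dissociation and stress response, and sex-linked genes.

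Alternatives fixed beforehand were DESeq2 size factors or no factor beyond total UMIs in place of TMM, the DESeq2 1.42.0 Wald test, no filter on low counts, no library block, a joint fit over all epithelial classes, clusters from a random part of the UMIs with values from the other part, Scrublet calls kept, a mitochondrial limit of 10%, at least 1000 genes per cell, Leiden resolutions of 0.5 and 2.0, each library clustered by itself, and each library left out in turn; for the libraries, a 2-fold rule, at least 10 UMIs, TMM factors, the deeper library thinned and the 10% limit. Those added after the data were seen were the removal of the 6% highest Scrublet scores, the restriction to cells with at least 0.1% Malat1 UMIs, and the rare classes. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, igraph 0.11.9 and matplotlib 3.10.9.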

Results

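Chrm3 and Chrm1, the genes of the M3 and M1 muscarinic acetylcholine receptors that are the subject of the series, were compared between epithelial classes of 2 control libraries from the proximal small intestine. Enterocyte-like cells made up 46.4% (95% interval 45.2% to 47.5%, 3298 cells) of control 1 and 47.7% (46.3% to 49.2%, 2250 cells) of control 2, and progenitor-like cells made up 10.2% (9.55% to 10.97%, 729 cells) and 7.23% (6.51% to 8.01%, 341 cells). Goblet-like cells, the mucus-secreting class, were 1.76% (1.46% to 2.09%, 125 cells) in control 1 and 5.39% (4.76% to 6.07%, 254 cells) in control 2. Paneth-like cells of the crypt base were 0.225% and 0.276%, hormone-secreting enteroendocrine-like cells 0.337% and 0.255%, and chemosensory tuft-like cells 0.267% and 0.170%, each from 8 to 24 cells. T or NK cell-like cells made up 37.0% and 35.4%, myeloid-like cells 2.56% and 1.68%, and B or plasma cell-like cells 0.351% (0.228% to 0.518%) and 1.12% (0.843% to 1.47%). Erythroid-like cells were 0.548% and 0.552%, and 0.394% and 0.233% stayed unnamed. Shares were not tested, since there is 1 group of 2 libraries, and the intervals cover counting of cells only. The progenitor share, 8.74% on average over the libraries, was not stable. It was 4.92% when the 5 and 28 cells called doublets were kept in and 3.15% without the 6% of cells with the highest doublet scores. Results for progenitor-like cells depend on where the clustering draws this class.

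**Figure D1:**
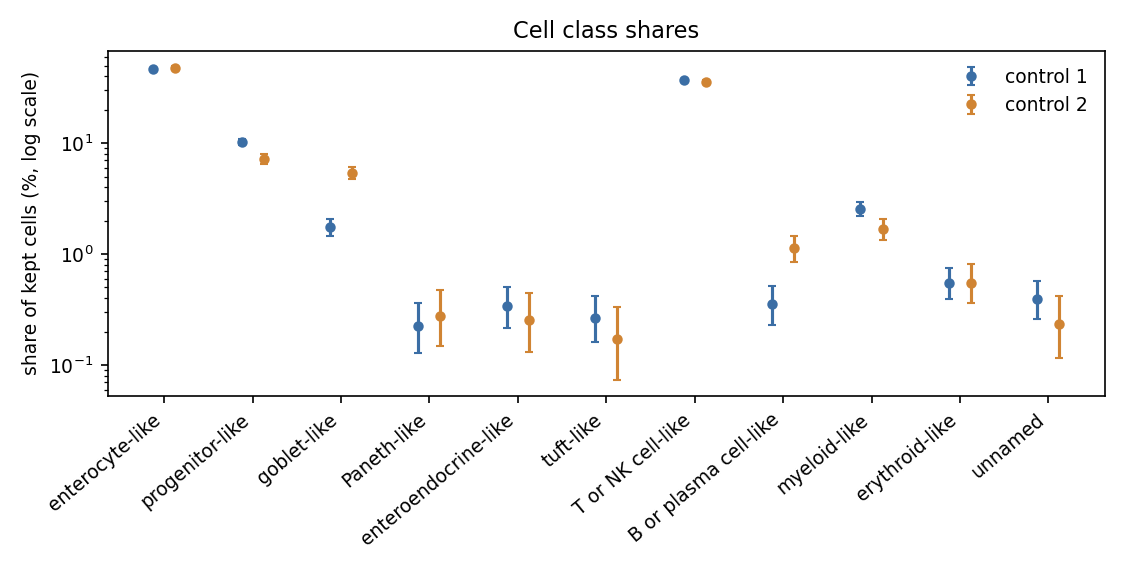
Share of kept cells (percent, log scale) of each named class in control 1 and control 2, with exact 95% Clopper-Pearson intervals; goblet-like cells were 1.76% and 5.39%.

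Chrm3 was highest in goblet-like cells, at 316 CPM (counts scaled to the UMI total of the class, 95% Poisson interval 289 to 345) in control 1 and 315 (297 to 335) in control 2. All other epithelial classes together were at 17.8 ± 1.42 CPM (mean and standard deviation over the 2 libraries). Against them the log2 fold change in goblet-like cells was 4.44 ± 0.19 (standard error, n = 2 libraries, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.62e-05). Chrm1 was lower in level but also highest there, at 13.9 (8.71 to 21.03) and 18.2 (13.9 to 23.3) CPM from 22 and 61 UMIs, with a log2 fold change of 5.78 ± 0.40 (adjusted p = 0.000285). Of the Chrm3 UMIs of the epithelial classes, goblet-like cells held 48.8% in control 1 and 81.0% in control 2, and of the Chrm1 UMIs 73.3% and 91.0%. The mean Chrm3 level of goblet-like cells was 71.0 times that of enterocyte-like cells (38.4 times that of their Malat1-rich part), 8.40 times that of progenitor-like cells and 2.69 times that of Paneth-like cells. The ratio to progenitor-like cells is smaller for their Malat1-rich part, which had a mean Chrm3 level of 74.9 CPM against 315 in goblet-like cells. Of the 2 muscarinic genes tested in goblet-like cells, 2 were higher and 0 lower, and 2 were higher when adjusted over the list alone.

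At least 1 Chrm3 UMI was found in 64.0% and 66.9% of goblet-like cells (median depth 6848 and 8692 UMIs), against 4.87% and 4.14% of T or NK cell-like cells (median depth 5086.5 and 4394 UMIs), a class outside the epithelium. After thinning to 2000 UMIs per cell, the shares were 41.6% and 38.4% of the 104 and 236 goblet-like cells deep enough, against 2.67% and 2.27% of 2213 and 1283 T or NK cell-like cells. Chrm1 UMIs were in 14.4% and 15.4% of goblet-like cells, 4.50% and 2.88% after thinning, with 0 and 1 Chrm1 UMI in all T or NK cell-like cells. The Chrm3 shares of enterocyte-like cells (1.24% and 1.16%; thinned 0.283% and 0.335%) and of progenitor-like cells (3.57% and 2.93%; thinned 1.03% and 1.42%) were below those of T or NK cell-like cells. The Chrm3 level of progenitor-like cells was nevertheless above theirs, at 43.0 (37.6 to 48.9) and 32.1 (24.9 to 40.9) against 16.1 (14.1 to 18.4) and 14.8 (12.2 to 17.7) CPM, so these shares do not mark it as background.

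Paneth-like cells were next, with Chrm3 at 110 (92.1 to 130) and 125 (104 to 148) CPM from 134 and 128 UMIs, and a log2 fold change of 2.51 ± 0.33 (adjusted p = 3.36e-12). These UMIs came from 10 of 16 cells in control 1 and 3 of 13 cells in control 2. The goblet-like fold change was larger and had a smaller standard error, yet a larger adjusted p. The smaller p-value here thus does not make the Paneth-like result firmer. The Paneth-like fold change depended on the scaling, being 1.32 with total UMIs only, and the call ended when each library was clustered by itself (1.44, adjusted p = 0.264), where the name covered 17 and 145 cells. The Paneth-like cluster also carried the stem cell markers Lgr5 (64.8 and 269 CPM) and Olfm4 (1144 and 1475 CPM), near or above the smaller progenitor-like cluster (85.3 and 31.0, and 2169 and 1284), so a mixture with such cells is not excluded for its results. Enterocyte-like cells were lower in Chrm3 (5.42 and 3.47 CPM; log2 fold change -4.45 ± 0.46, adjusted p = 0.00068) and in Chrm1 (0.197 and 0.0890 CPM; -4.51 ± 0.70, adjusted p = 0.00274). Of the Chrm3 UMIs 103 of 110 and 31 of 39 came from a cluster of 248 and 200 cells with a high mitochondrial share, at 9.33 and 5.80 CPM. The call for Chrm1 ended in the joint fit over all epithelial classes (-1.27, adjusted p = 1.00). That fit cannot decide this difference, since enteroendocrine-like and tuft-like cells had 0 Chrm1 UMIs and weigh there as much as any class. In progenitor-like cells Chrm3 was at 43.0 and 32.1 CPM (-0.80 ± 0.26, adjusted p = 0.00835) and Chrm1 at 0.369 and 2.43 CPM, the latter from 5 UMIs in 1 cell (-1.46 ± 0.61, adjusted p = 0.0409). The Chrm3 UMIs of this class came almost all from the smaller of its 2 clusters, 233 of 233 and 63 of 66, at 65.4 and 48.9 CPM in 211 and 91 cells. The larger cluster, of 518 and 250 cells, had 0 and 3 UMIs. In enteroendocrine-like cells Chrm3 was at 36.7 and 45.2 CPM from 20 and 13 UMIs (-0.94 ± 0.40, adjusted p = 0.0477). These 3 small differences are not firm: without the library block the adjusted p was 0.0938 for Chrm3 and 0.198 for Chrm1 in progenitor-like cells and 0.0825 for Chrm3 in enteroendocrine-like cells. As a log2 ratio within control 1 alone (1 CPM added, no TMM factors, so not on the scale of the fits), Chrm3 was at 0.37 in progenitor-like and 0.075 in enteroendocrine-like cells. Below 10% mitochondrial UMIs Chrm3 in enterocyte-like cells was at -7.25, and at Leiden resolution 0.5 Chrm3 in progenitor-like cells was at -5.53. In tuft-like cells Chrm3 was at 79.6 and 14.8 CPM from 27 and 2 UMIs, with no difference detectable at this depth (-0.26 ± 0.58, adjusted p = 0.889). Chrm1 did not differ detectably in Paneth-like cells (2 and 0 UMIs; -0.09 ± 1.42, adjusted p = 0.972).

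No Chrm1 UMI was found in enteroendocrine-like or tuft-like cells, where the upper 95% limits were 6.77 and 12.8, and 10.9 and 27.3, CPM. In control 1 the tuft-like limit lies below the goblet-like level of 13.9 CPM, though above its lower bound of 8.71. In control 2 the tuft-like limit lies above the goblet-like level of 18.2 CPM, so such a level is not excluded there. Overlap of intervals does not decide for control 1, and the 2 classes were not tested against each other. Chrm2 and Chrm5 had 0 UMIs in all classes and Chrm4 had 1 UMI in progenitor-like and 1 in T or NK cell-like cells, so M2, M4 and M5 receptor genes were not detectable at this depth. The enzyme that makes acetylcholine, Chat, was found in tuft-like cells, with 26 and 13 UMIs (76.7 and 96.1 CPM) in 6 of 19 and 4 of 8 cells. Its count ratio to the other classes was 1933 (500 to 16524), with a log2 fold change of 10.30 ± 0.80 (adjusted p = 2.9e-34). Outside that class Chat had 2 UMIs in enterocyte-like cells of control 1 and 0 elsewhere.

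By GENCODE M21 coordinates on GRCm38, Chrm3 lies on chromosome 13 from 9875486 to 10360847 on the minus strand, spans 485362 bases with 6253 exon bases, and overlaps 6 other annotated genes, among them the antisense gene Gm26861. Chrm1 lies on chromosome 19 from 8663789 to 8683587, Chrm2 on chromosome 6 from 36388084 to 36528414 and Chrm4 on chromosome 2 from 91927249 to 91928688, all on the plus strand. Chrm5 lies on chromosome 2 from 112479171 to 112480769 and Chat on chromosome 14 from 32408203 to 32465989, both on the minus strand. Whether intronic reads and reads of overlapping genes entered the Chrm3 count was not given in the sources used here, so its level is less certain than that of Chrm1. The p-values measure only how far the class-to-rest ratio differed between the 2 libraries. There is no replicate check between the libraries themselves, and adding cells adds no replicates.

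**Figure D2:**
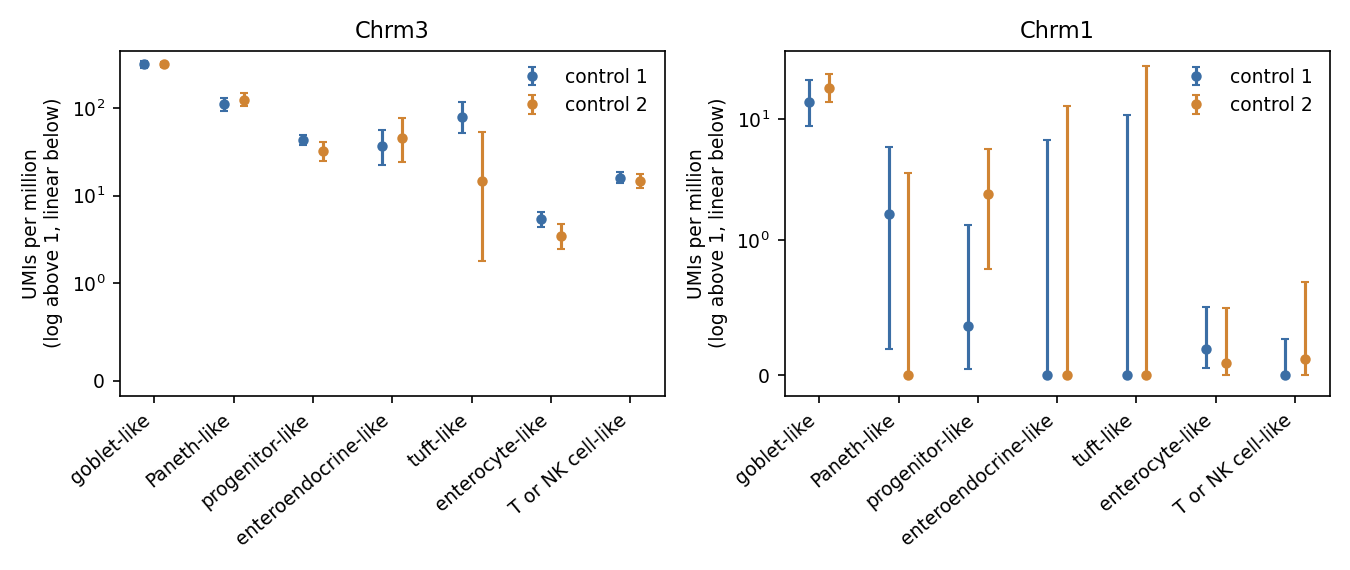
Chrm3 and Chrm1 CPM of each class (log scale above 1, linear below) in control 1 and control 2, with exact 95% Poisson intervals; goblet-like cells had 316 and 315 for Chrm3.

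Genes that act downstream of Gq-coupled receptors such as M1 and M3 went both ways in goblet-like cells. Plcb1, a phospholipase C, was at 223 ± 34.1 CPM against 9.61 ± 2.15 (log2 fold change 4.84 ± 0.18, adjusted p = 7.61e-05). Rgs2, which restrains Gq, was at 257 ± 18.4 against 18.2 ± 5.39 (4.14 ± 0.26), and Gnaq, the Gq alpha subunit, at 210 ± 19.6 against 54.2 ± 14.7 (2.27 ± 0.17). Itpr3, an IP3-gated calcium channel, was at 80.1 ± 23.97 against 26.2 ± 4.70 (1.89 ± 0.17). Gna11, another Gq family alpha subunit, was lower (83.4 ± 38.4 against 646 ± 139 CPM, -2.73 ± 0.21), as was the phospholipase C gene Plcb3 (-1.60 ± 0.17), whose call ended in the joint fit. Of 23 tested genes of Gq and calcium signalling, 11 were higher, 6 lower and 6 not past the threshold (13 and 7 adjusted over the list alone). Ache, which breaks down acetylcholine, was higher (5.50 ± 0.64 against 1.20 ± 0.02 CPM, 2.48 ± 0.48, adjusted p = 0.00698), and the acetylcholine handling list had 3 higher, 4 lower and 3 not past (3 and 5 adjusted over the list alone). Of the nicotinic subunits only Chrnb1 had enough UMIs, and it was higher (log2 fold change 1.65 ± 0.43, adjusted p = 0.0215; 1 higher adjusted over the list alone). That call ended with the DESeq2 Wald test (adjusted p = 0.103). Gi and adenylyl cyclase genes had 3 higher, 1 lower and 4 not past (3 and 1 adjusted over the list alone).

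Among secretory lineage transcription factors, Atoh1, which specifies secretory cells, was at 216 ± 9.64 against 3.13 ± 1.62 CPM in goblet-like cells (6.50 ± 0.30, adjusted p = 9.18e-05). Foxa3 was at 239 ± 14.9 against 6.49 ± 0.93 (5.49 ± 0.19) and Creb3l1 at 123 ± 14.0 against 6.58 ± 0.10 (4.52 ± 0.18). The list had 7 higher, 2 lower and 6 not past (7 and 2 adjusted over the list alone). The Notch ligand gene Dll4 (4.79 ± 0.21), the EGF receptor ligand gene Btc (4.47 ± 0.22) and the long-chain fatty acid receptor gene Ffar4 (5.62 ± 0.33) were higher. Wnt and Notch niche genes had 7 higher, 3 lower and 7 not past (7 and 3 adjusted over the list alone), and ErbB ligands and receptors 8, 2 and 3 (9 higher and 2 lower adjusted over the list alone). Kcnq1, a potassium channel gene, had 0 UMIs in goblet-like cells against 34.8 ± 5.13 CPM, at least 59.1-fold lower, and the chloride channel gene Cftr was at 3.29 ± 3.39 against 66.8 ± 15.1 (-4.37 ± 0.41, adjusted p = 0.000552). Ion transport and fluid secretion had 2 higher, 14 lower and 3 not past (2 and 15 adjusted over the list alone). The dissociation and stress list had 7 higher and 1 lower of 16 (7 and 1 adjusted over the list alone). The interferon list had 7 higher and 0 lower of 16 (7 and 0 adjusted over the list alone). Gbp2, a GTPase of cell defence, was at 15.8 ± 6.28 against 1.25 ± 0.44 CPM (3.94 ± 0.33). All 7 tested class II antigen presentation genes were lower, with the invariant chain gene Cd74 at -3.06 ± 0.60 (7 adjusted over the list alone). In the goblet-like class 11243 genes were tested, of which 2619 were higher and 2896 lower, and of the 238 list genes 69 were higher and 103 lower. A joint fit over all epithelial classes, each against the mean of the others, had 28 list genes lower, 25 of them among these, and 13 of 35 named goblet results lost the threshold there, among them Cd74. Kcnq1 lost it with the DESeq2 Wald test.

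**Figure D3:**
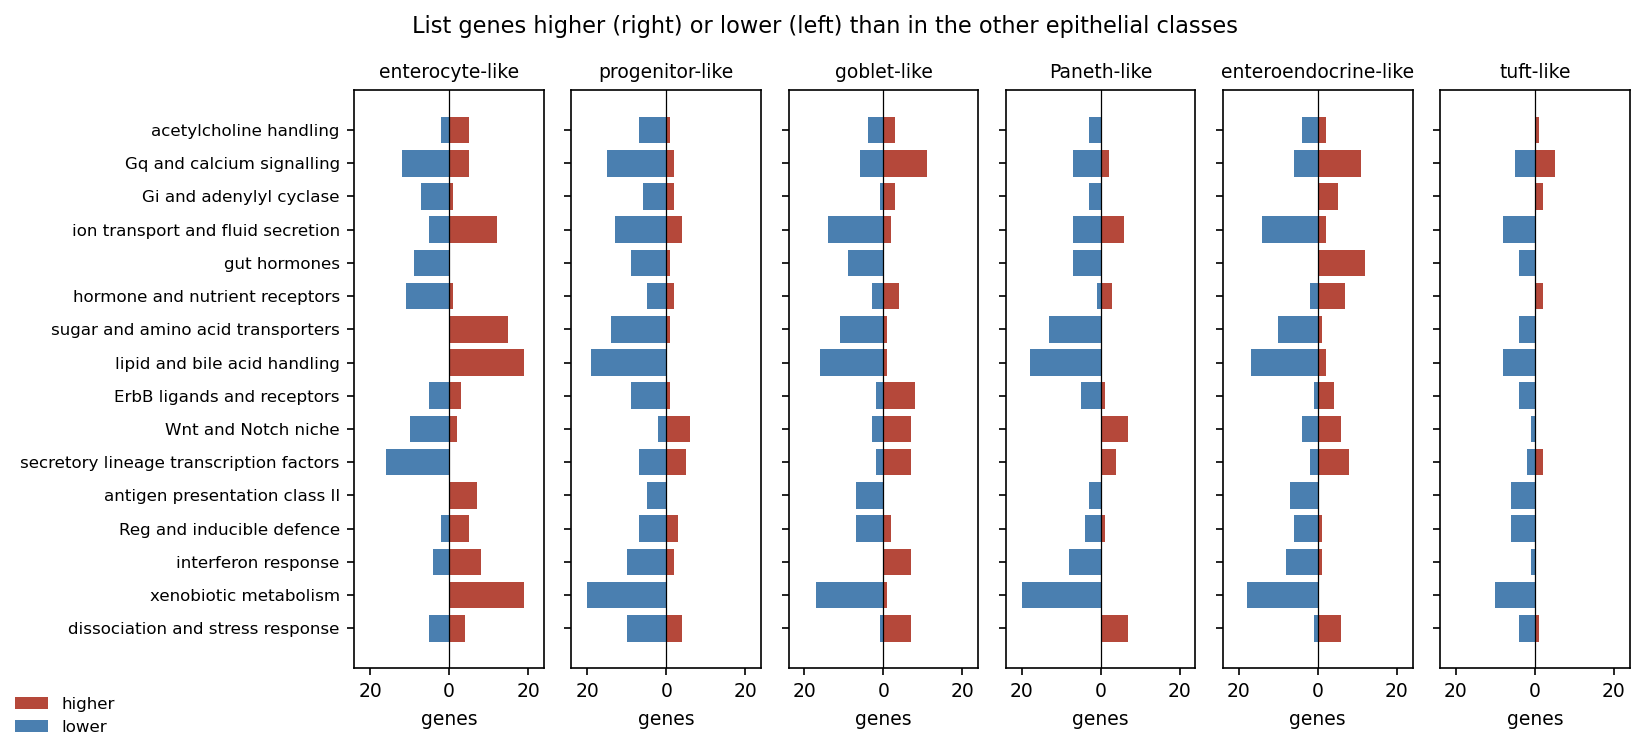
Number of tested genes per fixed list that were higher or lower in each epithelial class (adjusted p under 0.05, edgeR quasi-likelihood, Benjamini-Hochberg); of 23 tested Gq and calcium signalling genes 11 were higher in goblet-like cells.

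In enterocyte-like cells, the absorptive class, most tested genes of the lists for nutrient transport, lipid handling and xenobiotic metabolism were higher. Slc2a2, the GLUT2 sugar transporter, was at 237 ± 98.7 against 9.62 ± 7.83 CPM (log2 fold change 5.24 ± 0.26, adjusted p = 0.000188). Slc5a1, the sodium-glucose cotransporter, was at 885 ± 98.5 against 60.6 ± 32.5 (4.41 ± 0.22). Mttp and Apob, which load and form lipoproteins, were at 4.38 ± 0.28 and 4.21 ± 0.33 in log2 fold change. Cyp3a11, a cytochrome P450, was at 680 ± 226 against 39.4 ± 34.9 (4.84 ± 0.31). Of 16 tested sugar and amino acid transporters 15 were higher and 0 lower, of 20 lipid and bile acid genes 19 and 0, of 20 xenobiotic metabolism genes 19 and 0, and of 7 class II genes 7 and 0. Cd74 was at 739 ± 137 against 164 ± 35.3 CPM (2.62 ± 0.18). Adjusted over the list alone, these numbered 15 and 1, 19 and 0, 19 and 0, and 7 and 0. Gut hormone genes had 0 higher and 9 lower of 10, secretory lineage factors 0 and 16 of 17, and hormone and nutrient receptors 1 and 11 of 13 (0 and 9, 0 and 16, and 1 and 11 adjusted over the list alone). Nrg1, an ErbB ligand gene, was at 0.326 ± 0.04 against 140 ± 71.8 (-8.29 ± 0.33). Ffar1, a fatty acid receptor gene, was at least 50.7-fold lower. Reg1, a secreted lectin gene, was at 4287 ± 1966 against 181 ± 91.7 CPM (5.03 ± 0.16). The Reg and inducible defence list had 5 higher, 2 lower and 4 not past (5 and 2 adjusted over the list alone). In the class 11727 genes were tested, with 3405 higher and 2977 lower, and of 250 list genes 106 were higher and 91 lower. Most enterocyte-like UMIs of control 1, 11043431 of 20295840, came from a cluster of 248 cells (5340597 of 11236813 from 200 cells in control 2) with a median of 9.90% and 15.0% mitochondrial UMIs. Below 10% mitochondrial UMIs per cell, 58 list genes were higher, the calls for Slc2a2 in enterocyte-like cells (0.37, adjusted p = 0.315) and Slc5a1 in enterocyte-like cells (0.31, adjusted p = 0.345) ended, and Mttp in enterocyte-like cells (-0.28) and Reg1 in enterocyte-like cells (-0.22) turned direction. In the joint fit 18 of 33 named enterocyte results lost the threshold, among them Nrg1 and Ffar1, and 32 list genes were lower, 27 of them among the 91.

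In progenitor-like cells the transcription factor gene Sox4 was at 129 ± 28.7 against 13.0 ± 2.58 CPM (log2 fold change 2.88 ± 0.22, adjusted p = 2.73e-13) and Sox9, another transcription factor gene, at 76.0 ± 8.32 against 14.0 ± 0.27 (2.01 ± 0.22). Kcne3, a potassium channel subunit gene, was at 131 ± 26.9 against 5.41 ± 1.34 (4.18 ± 0.25). Neurog3, an endocrine lineage factor, was at 13.3 ± 7.35 against 0.645 ± 0.322 (3.89 ± 0.43). The serotonin receptor gene Htr4 was at 38.5 ± 1.29 against 2.35 ± 0.55 (3.63 ± 0.27), and the receptor gene Notch1 at 19.8 ± 1.63 against 2.96 ± 0.655 (2.33 ± 0.30). Cyp3a11 was at -5.72 ± 0.35 in log2 fold change and Cyp1a1, another cytochrome P450, had 0 UMIs, at least 25.5-fold lower. Of the xenobiotic list 0 were higher and 20 lower of 20 (0 and 20 adjusted over the list alone). Of the dissociation and stress list 4 and 10 of 16 were higher and lower (5 and 10 adjusted over the list alone), and of the Wnt and Notch list 6 and 2 of 19 (6 and 2 adjusted over the list alone). Of 11752 tested genes 3394 were higher and 3338 lower, and of 244 list genes 34 were higher and 161 lower. Below 10% mitochondrial UMIs the list counts were 59 and 95 and 12 of the 33 named results turned direction, among them Reg1 from -4.01 to 1.74 and Slc2a2 from -5.55 to 1.09. The call for Cyp3a11 in progenitor-like cells ended there (-0.49, adjusted p = 0.167). In the joint fit 10 of the 33 lost the threshold, among them Cyp1a1. At Leiden resolution 0.5 Htr4 in progenitor-like cells (-2.60) and Cftr in progenitor-like cells (-2.47, from 1.67 ± 0.22) turned as well.

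The rare classes were tested only after the data had been seen, and their p-values cannot be ranked against those of the other classes. In Paneth-like cells Wnt3, a stem cell niche signal, was at 25.4 ± 0.09 against 1.08 ± 0.12 CPM (log2 fold change 5.72 ± 0.50, adjusted p = 8.87e-28). Bhlha15, a factor of secretory cells, was at 5.52 ± 0.84, Sox9 at 3.51 ± 0.34, Notch1 at 3.25 ± 0.46 and Nr4a1, an immediate early gene, at 4.65 ± 0.68. Rgs2 was at least 35.0-fold and Tph1, which makes serotonin, at least 32.8-fold lower. Of 237 list genes 32 were higher and 99 lower of 11026 tested genes in all (1059 higher, 1984 lower), and the dissociation and stress list had 7 higher and 0 lower of 16 (7 and 0 adjusted over the list alone). In enteroendocrine-like cells all 12 tested hormone genes were higher (12 adjusted over the list alone), with Ghrl, the ghrelin gene, at 11.79 ± 1.10, Gcg, the proglucagon gene, at 9.91 ± 0.56 and Cck, the cholecystokinin gene, at 9.63 ± 1.17. Nrg1 was at 2508 ± 556 against 2.94 ± 3.68 CPM (9.72 ± 0.66). The factors Pax6 and Isl1 were at 8.95 ± 0.51 and 8.37 ± 0.50, the Gi and adenylyl cyclase genes Adcy2 and Gnao1 at 8.33 ± 0.51 and 7.57 ± 0.46, and Ffar1 at 7.06 ± 0.62. The somatostatin receptor gene Sstr5 was at least 411-fold higher. Of 246 list genes 70 were higher and 101 lower of 11696 tested (1961 higher, 2512 lower). In tuft-like cells Gfi1b, a tuft cell factor, was at 10.62 ± 0.93, the succinate receptor gene Sucnr1 at 10.23 ± 0.80, and Ffar3 at 9.30 ± 0.71. Adcy5 was at 9.29 ± 0.77, Plcb2 of taste signalling at 7.82 ± 0.66, Itpr2 at 4.53 ± 0.58, the calcium pump gene Atp2a3 at 4.51 ± 0.65 and Sox9 at 4.45 ± 0.60. Cd74 was at -4.90 ± 0.71, Ghrl at least 80.0-fold and the receptor gene Egfr at least 16.5-fold lower. Of 239 list genes 13 were higher and 63 lower of 11101 tested (496 higher, 437 lower). The count of lower list genes was not stable, at 22 with DESeq2 and in the joint fit, 21 without the library block, 104 with Scrublet calls kept, below 10% mitochondrial UMIs or without the highest doublet scores, and 135 with at least 1000 genes per cell. In the joint fit 13 of 32 named Paneth, 1 of 30 enteroendocrine and 9 of 30 tuft results lost the threshold, among them Tph1 in the Paneth-like class, and with DESeq2 Rgs2 in the Paneth-like and Ghrl in the tuft-like class did. With total UMIs only, the median log2 fold change of all tested genes went from -0.16 to -1.35 in the Paneth-like class and from -0.17 to 0.48 in the enteroendocrine-like class. The part of the passing list genes that were higher went from 24.4% to 10.9%, from 40.9% to 51.7% and, in the tuft-like class, from 17.1% to 27.6%.

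Between the libraries there is no test, with 1 library each, and the values are descriptive. Over all kept cells 114 of 13571 genes with at least 50 UMIs were at least 4-fold higher in control 2 and 97 in control 1, among them 6 and 5 list genes. The ratios depend on scaling, since with TMM factors 47 named ratios moved beyond their counting interval and 29 did not. The Paneth cell defensin gene Defa36 was at 9.44 CPM (8.56 to 10.4) in control 1 and 431 (423 to 439) in control 2, the mast cell protease gene Mcpt1 at 2.78 and 56.0, and Il31ra at 1.63 and 118. The somatostatin gene Sst was at 1.29 and 19.0, the neurotensin gene Nts at 1.69 and 12.2, Ffar4 at 1.45 and 8.21. Egfr was at 29.7 and 133, the antimicrobial lectin gene Reg3b at 214 and 1151, and Duox2, which makes hydrogen peroxide, at 0.534 and 4.53. Higher in control 1 were Grik3 (32.7 and 0.258), Ghrl (494 and 62.3), Akr1c19 (137 and 17.8), the substance P gene Tac1 (8.82 and 0.553), the fructose transporter gene Slc2a5 (44.4 and 10.2) and the ileal bile acid binding gene Fabp6 (3.21 and 0.147). Values over all cells also follow the class shares and single cells: Ffar4 had 43 and 188 UMIs in goblet-like cells against 11 and 28 in the other epithelial classes. Ghrl had 21924 and 1658, Sst 16 and 496 and Nts 61 and 314 UMIs in the 24 and 12 enteroendocrine-like cells. Within enterocyte-like cells 106 of 9747 genes were higher in control 2 and 56 in control 1. Some clusters of this class differed in size between control 1 and control 2, with 835 and 209, 515 and 129, and 47 and 256 cells. The largest had 749 and 766 cells. The values that follow thus mix levels with the make-up of the class. Reg3b was at 452 and 2644 CPM, Egfr at 23.7 and 154, the nucleoside transporter gene Slc28a2 at 113 and 578. Ido1, which breaks down tryptophan, was at 2.71 and 36.7, Duox2 at 0.0985 and 8.54, and the circadian gene Dbp at 32.7 and 1.78. Ido1 was also a leading gene of the goblet-like cluster. The goblet marker Muc2 was at 86.9 and 592 CPM in the enterocyte-like cluster with a high mitochondrial share. Goblet transcripts in enterocyte-like cells are thus not excluded for Ido1. Counts in the other classes were 21 and 51 in progenitor-like, 13 and 43 in goblet-like, 23 and 50 in T or NK cell-like, 105 and 6 in B or plasma cell-like, 24 and 55 in myeloid-like and 2 and 15 in erythroid-like cells, for control 2 and control 1 in turn. They are not firm either: with TMM factors the B or plasma cell-like counts turned, to 18 and 30, and erythroid-like cells had 6 genes higher in control 1. Below 10% mitochondrial UMIs 68 genes were higher in control 2 in enterocyte-like cells and 28 in control 1 in goblet-like cells. Among cells with at least 0.1% Malat1 UMIs the counts higher in control 1 were 31 in progenitor-like, 23 in goblet-like, 16 in B or plasma cell-like and 5 in erythroid-like cells. The 2-fold rule and the limit of 10 UMIs raised the counts in every class. Of the sex-linked list, Xist was at 0.223 and 0.0737 CPM and the Y-linked genes Ddx3y at 59.1 and 42.9, Eif2s3y at 62.2 and 47.1, Kdm5d at 17.6 and 24.3 and Uty at 57.9 and 59.9, with none past the size rule. Between classes 2 of its 4 tested genes were higher in goblet-like and 2 in enteroendocrine-like cells, and 1 was lower in enterocyte-like and 1 in progenitor-like cells (2, 2, 1 and 0 adjusted over the list alone).

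The nuclear transcript Malat1 split the epithelial barcodes, as 83.7% and 70.0% of enterocyte-like, 80.9% and 71.8% of progenitor-like, and 28.8% and 13.0% of goblet-like cells had under 0.1% Malat1 UMIs. The shares were 87.5% and 61.5% in Paneth-like, 15.8% and 37.5% in tuft-like and 0% and 0% in enteroendocrine-like cells. Outside the epithelium they were 1.33% and 2.16% in T or NK cell-like, 36.0% and 22.6% in B or plasma cell-like, 63.7% and 62.0% in myeloid-like and 61.5% and 65.4% in erythroid-like cells. At the median depths of enterocyte-like cells, 2386 and 2325 UMIs, the 0.1% limit is only a few Malat1 UMIs. The side on which a cell falls thus also depends on counting error and depth. Enterocyte-like cells at or above it (Malat1-rich) had median depths of 1984 and 1815.5 UMIs, against 2428 and 2502.5 below it (Malat1-poor). Over all kept cells Malat1 was at 8074 and 13882 CPM, so the libraries differed in it as well. Within enterocyte-like cells the ratio was larger, with Malat1 at 2206 and 7389 CPM and the nuclear RNA Neat1 at 191 and 484 CPM.

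**Figure D4:**
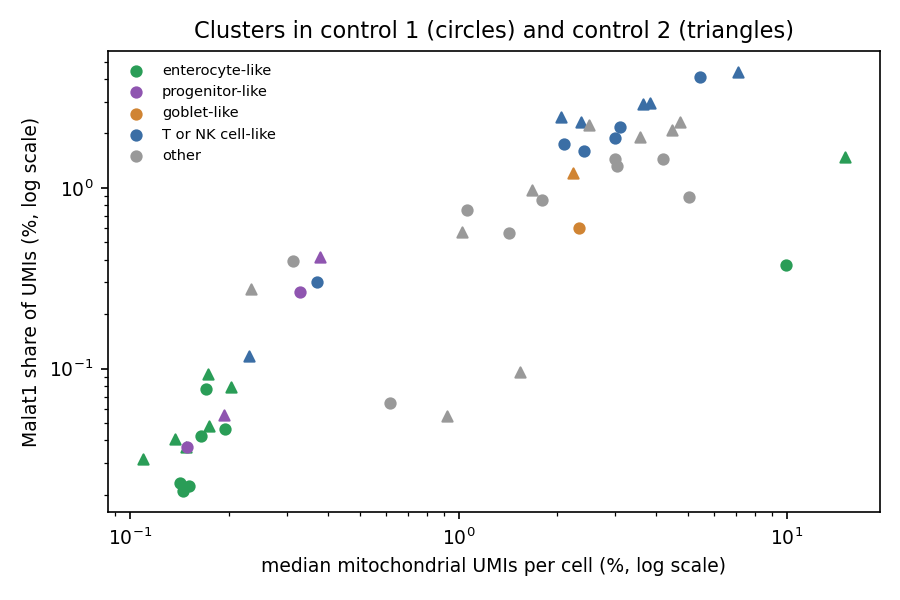
Malat1 share of UMIs (percent, log scale) against the median share of mitochondrial UMIs per cell (percent, log scale) of each cluster in control 1 (circles) and control 2 (triangles); the enterocyte-like cluster at the right had 9.90% and 15.0% mitochondrial UMIs.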

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

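Of the tests below, loss of nuclear RNA and a few cells were written before their results were seen; the other 6 of 8, and the values outside 1 cluster for loss of nuclear RNA, were chosen only after the result was seen. Chrm3 UMIs in T or NK cell-like cells, which entered no fitted comparison, stood above the limit that a count of 0 allows: 16.1 CPM in control 1 and 14.8 in control 2. Samples were of 1 group, so no biological explanation was tested for any pattern.

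The first pattern is this Chrm3 signal in T or NK cell-like cells. Free RNA was argued against, since the lower bound of the Chrm3 level there was 5.08 times the upper bound in Malat1-poor enterocyte-like cells in the library with the smaller ratio. Multiplets with goblet cells were also argued against, in the third test tried: the first, on Muc2 and written beforehand, was void because Muc2 named the clusters, and the second, the summed UMIs of Atoh1, Foxa3 and Creb3l1 per Chrm3 UMI in T or NK cell-like over goblet-like cells, left them open at 0.832 and 0.699. A multiplet brings every abundant transcript, and gene by gene this ratio was 0.0545 and 0.166 for Atoh1, 0.0745 and 0.116 for Foxa3 and 3.47 and 2.92 for Creb3l1, so the median gene was at 0.166 in the higher library (upper bound 0.300). Nuclear or intronic reads stay open: over 6 clusters Chrm3 and the Malat1 share had a Spearman rho of 0.771 in each library (exact two-sided permutation p = 0.103), but without the 2 clusters farthest from the median Malat1 share rho was 0.6 and 0.2, and clusters of a library are not independent.

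The second pattern is that most enterocyte-like and progenitor-like cells were poor in Malat1. Free RNA in empty droplets stays open: goblet, Paneth and T or NK marker genes held 0.0408 times the share of all kept cells there in control 1 and 0.0340 times in control 2, but the same markers named the clusters, which fixes a low ratio, and empty droplets were not used here. Loss of nuclear RNA fits: genes with the longest introns were lower than those with the shortest in Malat1-poor over Malat1-rich enterocyte-like cells by a median log2 difference of -1.31 in control 1 and -1.67 in control 2, and Neat1, another nuclear RNA, was at 58.2 against 384 and 36.2 against 843 CPM. Most of that size follows a cluster that also differed in mitochondrial RNA and held 91.0% and 85.2% of the Malat1-rich UMIs. Outside it the difference was -0.34 in control 1 and -0.14 in control 2. Of 100 shuffles within clusters the median was -0.10 and 0.012, and the lowest -0.26 and -0.074. Whether a cell counts as Malat1-rich also depends on its depth, so a part played by depth is not excluded. Outside that cluster Neat1 was at 15.0 against 64.9 and 35.8 against 103 CPM. Some of these cells may thus have lost nuclear RNA before capture, a hypothesis found and tested on the same cells, and it does not account for their mitochondrial RNA: the median mitochondrial share was 0.175% and 0.187% in enterocyte-like and 0.162% and 0.223% in progenitor-like cells against 2.32% and 2.23% in goblet-like cells, so another loss of RNA stays open as well.

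The last pattern is the Chrm3 and Chrm1 excess in goblet-like cells. The nuclear RNA content of the cells was argued against as its whole cause, since among cells with at least 0.1% Malat1 UMIs the log2 fold change of Chrm3 was 4.39. The other classes in that fit were mostly enterocyte-like UMIs, and Malat1-rich progenitor-like cells had Chrm3 at 96.4 and 53.5 CPM. Multiplets with cells of another named class were argued against for Chrm3, since a multiplet lies between its parts and the lower bound of the goblet-like level was 2.00 times the highest upper bound of any other class in the library with the smaller ratio. Doublet scores decide nothing here, because the doublet caller did not work in control 1, and multiplets with cells outside the named classes stay open. A few cells did not hold the excess by the bound written beforehand, 50%, yet they came near it: the 10% of goblet-like cells with the most Chrm3 UMIs held 46.6% of them in control 2 and 41.8% in control 1. Protein and receptor function were not measured.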

How the results depend on the processing

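The settings with at least 0.1% Malat1 UMIs, with the top 6% Scrublet scores removed and with the rare classes were chosen after the data were seen; the others were fixed beforehand. Chrm3 and Chrm1 stayed higher in goblet-like cells and past the threshold under every alternative with a test, at log2 fold changes of 3.45 to 4.47 and 5.25 to 6.87, and Chrm3 stayed lower in enterocyte-like cells at -7.25 to -3.74. Over 269 named results, those of the muscarinic receptors not counted, and 3484 alternatives, 3143 alternatives were the same, 129 lost the threshold, 184 moved and 28 turned direction, in 27 of the results. The 3143 include 193 with control 1 left out and 193 with control 2 left out. No test is left there, and the naming rule asked for the same direction in both libraries. That agreement was thus fixed by the rule, apart from the genes named after their values were seen. The lower Chrm3 and Chrm1 of progenitor-like cells and the lower Chrm3 of enteroendocrine-like cells were not kept under many settings, and neither was the progenitor-like class itself. Where no cause is named, the cause was not tested. Classes of 8 to 24 cells per library limit the depth for Paneth-like, enteroendocrine-like and tuft-like cells.

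With no replicate block, log2 fold changes were -1.62 for Chrm1 in progenitor-like cells (adjusted p = 0.198), -0.95 for Chrm3 in progenitor-like cells (0.0938) and -1.06 for Chrm3 in enteroendocrine-like cells (0.0825), and 21 list genes were lower in tuft-like cells. With the DESeq2 Wald test these were -1.58 (0.262), -0.89 (0.0592), -0.98 (0.214) and 22. With total UMIs only they were -1.03 (0.156), -0.37 (0.148) and -0.28 (0.590), with Chrm3 in tuft-like cells at 0.12 and 19 list genes higher and 156 lower in Paneth-like cells. With no filter on low counts Chrm1 in progenitor-like cells was at -1.54 (0.0506). With clusters from a random part of the UMIs and values from the other, Chrm1 and Chrm3 in progenitor-like cells were at -0.70 (0.456) and -0.47 (0.114), and Chrm3 in tuft-like cells at 0.034.

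In the joint fit against the mean of the other classes, in which each class weighs the same by construction, lower list genes numbered 32 in enterocyte-like, 83 in progenitor-like, 28 in goblet-like, 50 in Paneth-like, 47 in enteroendocrine-like and 22 in tuft-like cells, where 41 were higher. Chrm1 was at -1.27 in enterocyte-like (adjusted p = 1.00), 1.10 in progenitor-like and 2.61 in Paneth-like cells, and Reg1 in progenitor-like cells was at 0.10. The Chrm1 values are poorly determined, since the mean of the other classes includes enteroendocrine-like and tuft-like cells with 0 Chrm1 UMIs.

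With either library left out no test is left, and the values are log2 ratios within the other library with 1 CPM added and no TMM factors. They differ from the fitted values by this scale as well as by the library, so no difference is put down to the library alone. Ranges were 4.00 to 4.15 for Chrm3 and 3.53 to 3.77 for Chrm1 in goblet-like cells, -5.38 to -3.98 and -3.29 to -1.69 in enterocyte-like cells, -1.24 to 0.37 and -0.66 to -0.50 in progenitor-like cells, and 0.84 to 1.77 and -2.30 to 0.41 in Paneth-like cells. Chrm3 ranged from -0.67 to 0.075 in enteroendocrine-like and from -2.22 to 1.19 in tuft-like cells. Shares ranged from 46.4% to 47.7% for enterocyte-like, 7.23% to 10.2% for progenitor-like, 1.76% to 5.39% for goblet-like, 0.225% to 0.276% for Paneth-like, 0.255% to 0.337% for enteroendocrine-like, 0.170% to 0.267% for tuft-like and 35.4% to 37.0% for T or NK cell-like cells.

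With Scrublet calls kept, shares were 50.8% for enterocyte-like, 4.92% for progenitor-like, 0.376% for enteroendocrine-like and 32.2% for T or NK cell-like cells, Chrm1 and Chrm3 in progenitor-like cells were at -1.09 (adjusted p = 0.134) and -0.48 (0.166), and 104 list genes were lower in tuft-like cells. With the top 6% Scrublet scores removed, the progenitor-like share was 3.15% and the T or NK cell-like share 32.2%, Chrm3 in progenitor-like cells was at -0.49 (0.209), and 104 list genes were lower in tuft-like cells. At Leiden resolution 0.5 the shares were 51.3% for enterocyte-like, 4.57% for progenitor-like and 30.5% for T or NK cell-like cells, 22 list genes were higher in progenitor-like cells, and Htr4 in progenitor-like cells turned to -2.60, Cftr in progenitor-like cells to -2.47 and Isl1 there to 0.20. At resolution 2.0 the shares were 50.6%, 4.99% and 33.6%, with 0.384% enteroendocrine-like cells, and Chrm1 and Chrm3 in progenitor-like cells were at -1.14 (0.114) and -0.51 (0.106). With each library clustered by itself the shares were 51.3%, 3.20% and 31.6%, with 1.66% Paneth-like cells, 15 list genes were higher in Paneth-like cells and Chrm3 there was at 1.44 (0.264). That name took 17 and 145 cells, and whether this moved the values was not tested. Control 2 had no progenitor-like cluster, so this setting gave no progenitor-like fit.

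With cells under 10% mitochondrial UMIs, shares were 6.26% for progenitor-like, 0.374% for enteroendocrine-like and 30.5% for T or NK cell-like cells. List genes higher in enterocyte-like cells numbered 58, higher and lower in progenitor-like cells 59 and 95, and lower in tuft-like cells 104. Reg1 in enterocyte-like cells turned to -0.22 and Mttp to -0.28, and in progenitor-like cells Cyp1a1 turned to 0.52, Slc2a2 to 1.09, Cyp3a25 to 0.18, Slc15a1 to 0.34, Slc6a19 to 0.36, Apob to 0.19, Slc9a3 to 1.51, Slc27a4 to 0.12, Npc1l1 to 0.11, Reg1 to 1.74, Reg3b to 1.09 and Slc22a4 to 0.47. Between libraries, 68 genes were higher in control 2 in enterocyte-like and 28 in control 1 in goblet-like cells, and Cartpt in enterocyte-like cells turned to -0.17.

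With at least 1000 genes per cell, shares were 38.6% for enterocyte-like, 5.14% for progenitor-like, 0.426% for enteroendocrine-like, 0.486% for tuft-like and 41.5% for T or NK cell-like cells, and Chrm1 and Chrm3 in progenitor-like cells were at -1.22 (adjusted p = 0.117) and -0.62 (0.166). All 28 and 11 cells named tuft-like there were the unnamed cells led by Siglech, so its tuft values describe another cell type: 30 list genes higher and 135 lower, Chrm3 at -5.20 (9.50e-08), H2-DMa at 2.36, Ffar3 in tuft-like cells at -7.38, Cd74 at 1.77, H2-Aa at 2.27, Atp2a3 at -0.83, Sox9 at -11.12 and H2-Eb1 at 1.64. Ffar3 in enterocyte-like cells was at 2.55. With at least 0.1% Malat1 UMIs, shares were 19.9% for enterocyte-like, 3.73% for progenitor-like, 0.120% for Paneth-like, 0.560% for enteroendocrine-like, 0.318% for tuft-like and 66.6% for T or NK cell-like cells, since most enterocyte-like cells were removed. Chrm1 in progenitor-like cells was at -1.40 (0.0775), genes higher in control 1 numbered 31 in progenitor-like, 23 in goblet-like, 16 in B or plasma cell-like and 5 in erythroid-like cells, 0 were higher in control 2 in erythroid-like cells, and Iglc1 over all kept cells turned to -1.01.

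Between libraries, looser rules gave more genes by construction. With the 2-fold rule, control 1 and control 2 in turn had 422 and 507 over all kept cells, 302 and 492 in enterocyte-like, 151 and 101 in progenitor-like, 167 and 81 in goblet-like, 213 and 125 in T or NK cell-like, 33 and 281 in B or plasma cell-like, 262 and 52 in myeloid-like and 199 and 7 in erythroid-like cells. With at least 10 UMIs they had 282 and 282, 162 and 236, 247 and 94, 161 and 125, 185 and 105, 45 and 888, 459 and 118, and 307 and 14. With TMM factors 30 and 18 were higher in B or plasma cell-like cells and 6 in control 1 in erythroid-like cells. TMM factors moved 47 named ratios beyond their counting intervals and left 29, and thinning of the deeper library moved 37 and left 39.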

Other observations

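Chrm3 levels of Malat1-rich and Malat1-poor cells of the same class stood apart, which follows the clusters within the class only in part. In control 1 all 233 progenitor-like Chrm3 UMIs lay in the smaller cluster, 196 in Malat1-rich and 37 in Malat1-poor cells. That cluster held 3563939 UMIs and all Malat1-rich cells of the class held 2033817, so the gap was present within the cluster as well. In progenitor-like cells Chrm3 was at 96.4 CPM (83.4 to 111) in Malat1-rich and 10.9 (7.69 to 15.1) in Malat1-poor cells of control 1, and at 53.5 (41.1 to 68.4) and 3.43 (0.706 to 10.0) in control 2; in enterocyte-like cells it was at 10.7 and 1.83, and at 5.78 and 0.599. The smaller progenitor-like cluster had a Malat1 share of 0.266% and 0.414% and 233 of 233 and 63 of 66 Chrm3 UMIs, the larger a share of 0.0370% and 0.0551%, and 1 enterocyte-like cluster, at 0.375% and 1.49%, held 103 of 110 and 31 of 39. At Leiden resolution 2.0 the goblet-like class split into a larger cluster of 81 and 203 cells, with Chrm3 at 386 and 358 CPM and a Malat1 share of 0.736% and 1.36%, and a smaller cluster of 36 and 48 cells, with Chrm3 at 50.4 and 26.1 CPM and a Malat1 share of 0.0801% and 0.113%. Chrm1 was at 25.2 and 19.0 CPM in the smaller cluster. A cluster named stem there, of 178 and 78 cells, had Chrm3 at 71.9 and 56.98 CPM from 231 and 63 UMIs, against 0 to 5.43 in the cycling progenitor clusters. The Malat1 share of the stem cluster was 0.190% and 0.295%. A cycling progenitor cluster of 34 and 13 cells had a larger share, 0.958% and 1.13%, with 2 and 0 Chrm3 UMIs. Between these clusters Chrm3 thus did not follow the Malat1 share. These values and those below were chosen after the data were seen and were not tested. Butyrylcholinesterase, from the gene Bche, was at 119 (115 to 124) and 63.4 (58.8 to 68.2) CPM in enterocyte-like cells, against 13.3 and 11.01 in goblet-like cells, while Ache in enteroendocrine-like cells was at 3.67 CPM in control 1 and 52.2 in control 2.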
